A study of Mus musculus with 2343 samples.

How the data were processed

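RNA was measured in thymic epithelial cells of mice, the cells that form the niche in which T cells mature and are selected. The labels name cortical cells (cTECs) and the subset of medullary cells with high surface MHC class II (mTEChi). In the cells labelled Eed the strain name combines floxed Eed with beta5t-Cre. Eed encodes a subunit of Polycomb repressive complex 2 (PRC2), the enzyme complex that deposits H3K27me3. The mTEChi mice also carried a ZsGreen reporter, and Eed cells were sorted as ZsGreen negative (ZsGneg) or ZsGreen positive (ZsGpos). The strain names give no Cre driver for the wild-type (WT) cells.

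Per the labels' protocols, tissue was digested with Liberase and DNase I and TECs were sorted, and polyadenylated RNA was amplified with the SMART-seq2 protocol from single cells or from pools of about 1000 cells. Small pools held 100 cells, and 1 of them 70. The submitters' processing notes name FastQC, Trimmomatic, HISAT 0.1.6, BWA 0.5.9, HTSeq, MACS2 and the mouse build mm10. They do not give the role or the order of these tools, and the versions of the others are not given in the sources used here. The deposited table holds whole-number read counts per gene with no molecular identifiers, and the strand setting of the counting is not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies can therefore not be told apart.

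The table has 45317 gene rows, 92 rows for ERCC spike-in RNAs and 5 rows for reads that were not assigned. Of the gene names, 41743 matched a mouse symbol in the gene name table and 32165 the RefSeq annotation, from which the coordinates on GRCm38, the assembly that mm10 stands for, were taken. All 2319 columns used here were tied to samples by name. The 7 H3K27me3 ChIP and input samples have no column in the table and were not analysed here. A further 17 samples labelled as repeat sequencing runs also have no column, and whether the bulk columns hold 1 run or both is not given in the sources used here. Epop, a PRC2 accessory subunit, and Prxl2b, a cTEC gene, have no row.

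Bulk mTEChi libraries were grouped as ZsGpos (4), ZsGneg (4) and WT (9). The WT titles carry a number from 01 to 03 and an R number from 01 to 03. The 3 WT libraries of each number were summed, which gave 3 WT units, because the meaning of the R number is not given in the sources used here. No label says that units come from separate animals, so p-values measure only the spread between samples. All 3 groups entered 1 fit. Genes were kept by filterByExpr and scaled by TMM, and tested with the quasi-likelihood test of edgeR 4.0.16 with Benjamini-Hochberg adjustment at 0.05. A log2 fold change and its standard error (SE) come from that fit, and levels are gene counts scaled to a common library total (CPM) with the SD between units. A fold against a group without any count was computed against a floor of 3 counts over the whole group. With 1 to 3 counts the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

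Whether replicate numbers shared by groups pair the samples is not known. Correlations of deviations between ZsGneg and ZsGpos libraries of the same number lay between 0.004 and 0.018 over 4 pairs. Those of different numbers lay between -0.018 and 0.014. WT libraries of the same number had a mean of -0.114, against -0.129 for those of different number and R number. In both Eed groups, numbers 01 to 03 had high Y-linked genes and 04 high Xist. So weak a measure cannot exclude pairing, and the main fit was unpaired. The small-pool comparison used the 9 wells of plate 1373, the plate with 3 wells of each group, in the same kind of fit. Nothing says that these wells come from separate animals.

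A total of 30 gene lists was fixed before the data were examined, together with the tests, the groups, the named-gene rule and most of the other settings tried. The lists cover PRC2, PRC1, HOX genes, developmental transcription factors, transcription factors of thymus organogenesis, CDK inhibitors, cTEC genes, mTEC maturation, mTEC-low genes, tissue-restricted antigens, keratinised post-Aire cells, tuft, neuroendocrine, microfold, ciliated and muscle mimetic cells, MHC class II and class I presentation, interferon response, chemokines, cell cycle, p53 targets, Wnt, Bmp and Notch signalling, early response and stress, thymocytes, B cells, myeloid and dendritic cells, fibroblasts, endothelial cells and erythroid cells. Lists with at least 4 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera asks whether a list moved relative to all other genes. A second p used a correlation estimated for each list. Fry, which asks whether the members of a list moved at all, was an alternative. Members past the threshold over all genes tested are given beside those past it when adjusted over the list alone.

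Named genes were taken by a fixed rule. It named 15 genes in every comparison: Eed, Ezh1, Ezh2, Suz12, Cdkn2a, Cdkn2b, Foxn1, Aire, Fezf2, Cd80, H2-Aa, Ccl21a, Psmb11, Prss16 and Mki67. It added the 6 highest and 6 lowest fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes and pseudogenes, and up to 2 called members of each list. In single cells it took the 6 highest and 6 lowest ratios among genes of at least 50 CPM in the higher sum and detected in at least 10% of its cells, in mTEChi with 1 direction on all 4 plates.

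Of 2273 single-cell wells, 384 in each cTEC set, 469 ZsGneg, 540 ZsGpos and 496 WT mTEChi wells, a well was kept with at least 50000 gene counts and 1000 genes. This left 333 Eed and 272 WT cTECs, and 330 ZsGneg, 217 ZsGpos and 286 WT mTEChi cells. The mTEChi wells lie on 4 plates, 1373, 1379, 1380 and 1381, called A, B, C and D in the results. No plate label is given for the cTECs and no animal for any cell, so each group is 1 sample and the single-cell differences have no replicate check, p-value or SE. Counts were summed over cells, expressed as CPM, and compared as log2 ratios with 1 CPM added to both sides. Plates gave unequal numbers of cells to the mTEChi groups, for example 2 ZsGpos, 85 ZsGneg and 77 WT cells on plate D. Differences between plates can therefore enter the ratios of the summed mTEChi cells. A list median was placed among 10000 random lists of genes with matched mean expression. Shares of cells are given unthinned and with every cell thinned to 50000 counts. Cell types were scored as at least 3 detected markers per cell, from marker sets fixed at the same stage as the gene lists, without clustering. Wells were sorted singly, and no doublet caller was run.

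Other computations used R 4.3.3, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Results were recomputed with RLE size factors, the DESeq2 Wald test, no filter on low counts, other treatments of the WT libraries, the replicate number as a block, only the compared groups in the fit, leaving out each unit, other cell filters, thinning, the mean over cells and each plate alone. Settings chosen after seeing the data were a factor for sex-linked expression, the share of reads outside genes as a covariate, 1 WT library per number, small pools of all plates with at least 10000 counts, single cells without plate 1381, and plates on which both groups shared 1 sex-linked pattern.

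The procedures were tested on simulated counts drawn from the mean levels of the bulk units, of the small pools or of the summed single cells. Changed genes were picked above a minimum level, and each gene was drawn independently, so correlation between genes was left out. The simulated single-cell sums held counting error only, without differences between cells or plates. Of genes changed 2-, 4- and 8-fold, the bulk fit recovered 0, 20.9 and 53.0% for ZsGpos against WT, 1.5, 23.9 and 48.5% for ZsGneg against WT, and 3.0, 34.3 and 68.2% for ZsGpos against ZsGneg, with false calls at 0, 3.9 and 1.4% of the calls. In the small pools, over 731 genes, the recovery was 6.0, 55.2 and 80.3%, 16.4, 55.2 and 71.2%, and 14.9, 79.1 and 92.4%, with 2.1, 5.9 and 3.9% false calls. Camera called the raised list in each comparison, with adjusted p = 2.45e-07, 2.49e-08 and 3.99e-12, beside 1, 0 and 0 other lists. In simulated single cells 100% of the changed genes had the true sign, and 7, 4, 8 and 4% of unchanged lists lay outside the 95% range. Bulk changes of 2-fold were thus rarely detectable at this number of units.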

Results

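Gene expression was measured in sorted thymic epithelial cells from mice with floxed Eed, with or without a Cre driver active in the thymic epithelial lineage. The data hold bulk mTEChi libraries of about 1000 cells (4 ZsGpos, 4 ZsGneg and 9 WT, the latter summed to 3 units), small pools of 100 mTEChi cells, and single cTECs and mTEChi cells. Bulk libraries held between 10519116 and 14990893 gene counts. Single cells that passed the filters had medians of 516069 gene counts in Eed cTECs, 538740 in WT cTECs, 303038 in ZsGneg, 309825 in ZsGpos and 289438 in WT mTEChi cells.

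Eed, the targeted gene (chromosome 7, 89954654 to 89980976, GRCm38), encodes the PRC2 subunit that binds H3K27me3 and is needed for the activity of the complex. In the bulk units it had 53.9, 19.2, 90.1 and 16.7 CPM in ZsGpos cells, 77.1, 49, 101.1 and 53.4 CPM in ZsGneg cells and 52.1, 30.2 and 47 CPM in WT cells. These levels gave no call in any comparison: the log2 fold change was 0.06 for ZsGpos against WT (SE 0.56, adjusted p = 1) and -0.64 for ZsGpos against ZsGneg (SE 0.52, adjusted p = 0.611). In single cells it stood at 20.9 CPM in Eed cTECs (95% counting interval 20.3 to 21.7) and 34.2 CPM in WT cTECs (33.2 to 35.2). Among single mTEChi cells it had 25.3 CPM in ZsGpos (24.1 to 26.5), 46 in ZsGneg (44.7 to 47.3) and 39.4 in WT (38.1 to 40.7). In the small pools Eed was too low to test, at 17.3 ± 8.71 CPM in ZsGpos, 6.56 ± 11.4 in ZsGneg and 45.8 ± 57.7 in WT (SD, n = 3 wells each). Counts per gene do not separate floxed from remaining exons, so these levels do not show whether the deletion took place.

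Bulk ZsGpos cells, in which the Cre reporter was on, were compared with WT cells to ask which genes differed in the reporter-positive medullary cells of the mutant. Fos, an immediate early transcription factor (chromosome 12, 85473890 to 85477274, GRCm38), rose 16.6-fold, from 40.7 ± 14.2 to 676.2 ± 207.9 CPM (SD, n = 3 WT units and 4 ZsGpos units; log2 4.05, SE 0.348, adjusted p = 0.000297). Krt5, a keratin of basal epithelial cells and immature mTECs (chromosome 15, 101707069 to 101712905), rose from 124.4 ± 15.2 to 787.6 ± 97.2 CPM (log2 2.66, SE 0.263, adjusted p = 0.000872). Lgals2, a galectin of the gut epithelium expressed in mTECs as a self-antigen, fell from 198.1 to 18.99 CPM (log2 -3.38, SE 0.442, adjusted p = 0.00579). H2-Aa, the alpha chain of MHC class II (chromosome 17, 34282744 to 34287823), fell from 6338 ± 646 to 3451 ± 124.3 CPM (log2 -0.88, SE 0.128, adjusted p = 0.0101).

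Of 18931 genes tested, 72 passed the threshold, 24 higher and 48 lower in ZsGpos. With only the compared groups in the fit the balance turned, to 63 higher and 56 lower. Egr1, another immediate early factor, stood 7.51-fold above WT (log2 2.91, adjusted p = 0.00132), and Dusp1, a phosphatase that ends MAP kinase signals, rose from 17.2 to 198.2 CPM (log2 3.53, adjusted p = 0.00695). Stmn2, a tubulin regulator of neurons, rose from 9.53 to 125.8 CPM (log2 3.72, adjusted p = 0.0254). Krt14, the partner of Krt5 in basal filaments, rose from 110.2 to 310.7 CPM (adjusted p = 0.0157), and Hes1, a transcriptional target of Notch, from 42.8 to 186.7 CPM (adjusted p = 0.0195). The lower genes held tissue-restricted antigens, which mTECs display to delete self-reactive T cells. Resp18, a protein of endocrine cells, fell from 288.2 to 29.8 CPM (log2 -3.27, adjusted p = 0.0157). The gut peptides Tff3 (143.2 to 17.9 CPM, adjusted p = 0.0234) and Reg3g (2582 to 643.4 CPM, adjusted p = 0.0191) also fell. Sprr4, a cornified envelope protein, had no count in ZsGpos and 10.3 ± 1.38 CPM in WT (adjusted p = 0.0365), and the cystatin Cst9 had 0.0379 against 35.02 CPM (adjusted p = 0.0176). No call was made for Aire, the regulator of self-antigen expression (248.05 ± 33.6 against 210.2 ± 33.5 CPM, adjusted p = 1), its counterpart Fezf2 (377.2 against 527.8 CPM, adjusted p = 0.434), the costimulator Cd80 (log2 -0.75, adjusted p = 0.92) or Cdkn2a, a cell cycle inhibitor held silent by PRC2 in many tissues (4.04 ± 2.92 against 0.347 ± 0.38 CPM, adjusted p = 0.843). Foxn1, Suz12, Cdkn2b, Prss16 and Ezh2 differed by at most 0.22 on the log2 scale, and Ezh1, Ccl21a, Psmb11 and Mki67, with log2 fold changes of 1.41, 3.04, -2.07 and 0.41, had no call either. The calls of Fos, Egr1, Krt5 and Lgals2 held whichever unit was left out. Those of H2-Aa and Dusp1 were lost without WT 02 or WT 03 (adjusted p = 0.0556 to 0.0642), as was that of Resp18 (0.0642 to 0.0715). Krt14 lost its call without WT 01, 02 or 03 (0.0805 to 0.13), Hes1 without any of these or ZsGpos 04 (0.0624 to 0.167), and Cst9 without ZsGpos 01, 02 or 04 or WT 02 or 03 (0.0531 to 0.102). Stmn2 and Tff3 lost it without any 1 ZsGpos or WT unit (0.0564 to 0.178), Reg3g without any of these except WT 01 (0.0583 to 0.109), and Sprr4 without any 1 unit (0.0525 to 0.167). The share of tested genes past the threshold, 0.38%, was 0.247, 0.254 and 0.211% without ZsGpos 01, 02 and 04, and 0.166, 0.044 and 0.063% without WT 01, 02 and 03. With the share of reads outside genes as a covariate it was 0.037%, with Fos, Egr1 and Krt5 among the calls and H2-Aa (adjusted p = 0.138) and Lgals2 (0.103) not. H2-Aa hardly moved (log2 -0.86 against -0.88), while its SE rose from 0.128 to 0.168.

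**Figure D1:**
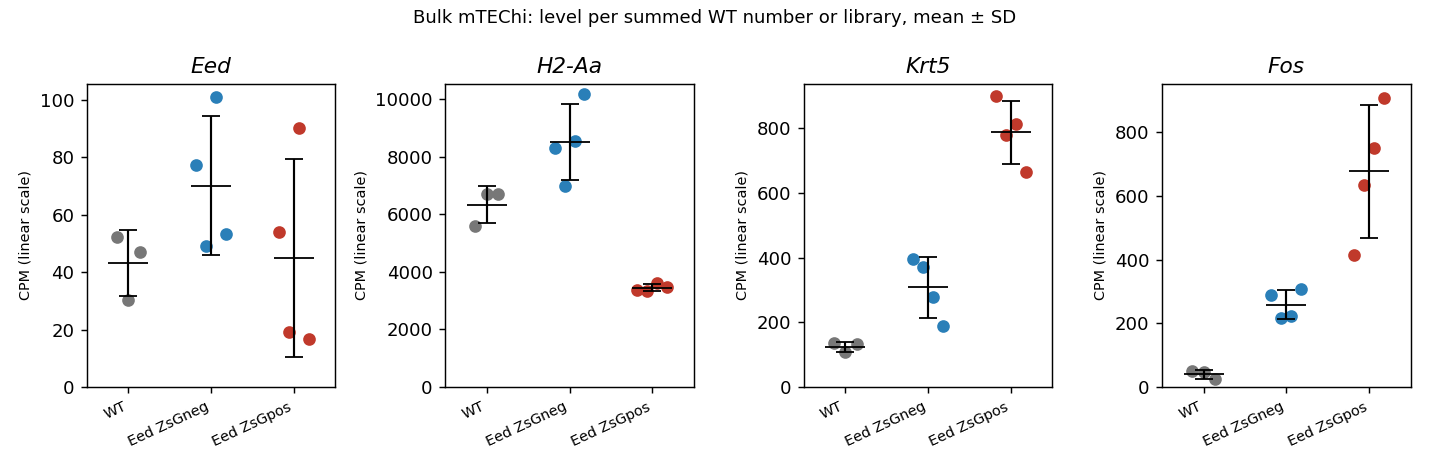
CPM of Eed, H2-Aa, Krt5 and Fos in each bulk mTEChi unit (points), with the mean and SD of each group; each axis is linear and starts at 0. Fos and Krt5 lay higher in ZsGpos than in WT units, H2-Aa lay lower, and the Eed values of the groups overlapped.

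Gene lists were tested in the same bulk comparison with camera. Early response and stress genes rose in ZsGpos (adjusted p = 5.3e-20, 6 of 16 members past the threshold and 11 when adjusted over the list alone), with Fos, Egr1, Dusp1, Jun and the near-identical copies Hspa1a and Hspa1b, whose reads cannot be told apart. The mTEC-low genes rose (1.12e-10, Krt5, Krt14 and Ly6a, 3 of 14 members, alone 8 higher and 1 lower). Wnt, Bmp and Notch signalling genes rose (3.59e-07, 1 of 33 members, Hes1, alone 2), and p53 targets rose (0.00151, 1 of 22, Btg2). Tissue-restricted antigens fell (4.26e-07, 3 of 37 members, alone 9). These 5 lists also passed with an estimated correlation, at adjusted p = 0.0121, 0.0129, 0.0129, 0.0261 and 0.0214. A further 8 lists passed camera but not that test: interferon response genes were higher (5.46e-07, no member, alone 7; adjusted p = 0.0593 with an estimated correlation), as were thymocyte genes (5.97e-06, alone 0; adjusted p = 0.056 with an estimated correlation), HOX genes (0.0135, none of 21; adjusted p = 0.0593 with an estimated correlation), fibroblast genes (0.0174; adjusted p = 0.139 with an estimated correlation) and developmental transcription factors (0.0273; adjusted p = 0.156 with an estimated correlation), although the member called in the last, the gut factor Cdx1, fell. Lower were erythroid (0.00416; adjusted p = 0.0659 with an estimated correlation), keratinised (0.0116; adjusted p = 0.142 with an estimated correlation) and MHC class II genes (0.0194, H2-Aa called, alone 8 of 13; adjusted p = 0.281 with an estimated correlation). The other 17 lists had adjusted p values from 0.0584 to 0.771: PRC2, PRC1, thymus organogenesis, CDK inhibitors, cTEC, mTEC maturation, tuft, neuroendocrine, microfold, ciliated, muscle, MHC class I, chemokines, cell cycle, B cell, myeloid and endothelial genes. Among these the cTEC, B cell, PRC1 and PRC2 lists gave opposite signs by camera and fry, and the endothelial list by its median and mean. Of the 39 HOX genes listed, 2 reached 5 CPM in WT units. Mitochondrial genes took 9.15 to 14.9% of gene counts in ZsGpos and 7.23 to 7.75% in WT units, without overlap.

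Bulk ZsGneg cells, from the same strain but with the reporter off, were compared with WT cells to ask what differed without reporter activity. Fos rose 6.35-fold to 258.6 ± 45.7 CPM against 40.7 ± 14.2 (SD, n = 4 and 3; log2 2.67, SE 0.324, adjusted p = 0.0203). Ifitm3, an interferon-induced membrane protein that restricts viruses, rose from 840.8 ± 53.3 to 2202 ± 478.6 CPM (log2 1.39, SE 0.192, adjusted p = 0.0286). Mdk, a heparin-binding growth factor, rose from 90.3 to 291.7 CPM, the interferon-induced Ifi27l2a from 242.4 to 710.0 CPM, the chaperone Clu from 340.9 to 732.8 CPM and Egr1 from 54.96 to 210.6 CPM, while Sgpl1, which degrades sphingosine 1-phosphate, fell from 525.1 to 220.7 CPM (adjusted p = 0.0451 for each of these 5). With Rps19, a ribosomal protein gene chosen after its values were seen (1554.5 to 3080.3 CPM, adjusted p = 0.0286), 8 genes passed: 7 higher and 1 lower, or 87.5% higher, against 100% higher with RLE size factors. The balance turned round with DESeq2 (42.7% higher) and with only the compared groups in the fit (0 higher and 1 lower). The share of reads outside genes was 18.9 to 24.04% in ZsGneg and 25.8 to 32.2% in WT units, without overlap, and with it as a covariate edgeR called 0 genes (925 at unadjusted p under 0.05). Eed (log2 0.70, adjusted p = 0.923), H2-Aa (8500 ± 1320 against 6338 ± 646 CPM, log2 0.42, adjusted p = 0.284), Aire (143.1 against 210.2 CPM, adjusted p = 0.428), Suz12 (log2 -0.95, adjusted p = 0.578), Cd80 (1.21, 0.502) and Psmb11 (-6.29, 0.331) had no call. The remaining named genes had none either. No call was stable to the choice of units: the Fos call was lost without ZsGneg 01, ZsGpos 02, WT 02 or WT 03 (adjusted p = 0.0594 to 0.143) and Ifitm3 without any 1 of 8 units (ZsGneg 01 to 03, ZsGpos 02 and 03, WT 01 to 03; 0.0506 to 0.377). Clu and Sgpl1 lost theirs without any 1 of the 11 units, Egr1 without any except ZsGpos 01, Ifi27l2a without any except ZsGneg 04 and Mdk without any except ZsGpos 03 (0.0562 to 0.385 over these genes). The share past the threshold, 0.042%, was 0% without ZsGneg 01, ZsGpos 02, WT 02 or WT 03 in edgeR (1944, 1750, 1618 and 1810 genes at unadjusted p under 0.05), and with all units DESeq2 gave 2.73%. It was 0.005, 0.016 and 0.027% without ZsGneg 02, 03 and 04, 0.021, 0.016 and 0.022% without ZsGpos 01, 03 and 04, and 0.019% without WT 01.

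By camera, 10 lists passed in ZsGneg against WT, and none of them passed with an estimated correlation. Higher were cell cycle genes (adjusted p = 2e-07, none of 34 members, alone 1; adjusted p = 0.07 with an estimated correlation), interferon response genes (2e-07, 1 of 26, Ifi27l2a, alone 8; adjusted p = 0.07 with an estimated correlation), mTEC-low genes (3.86e-07, alone 4; adjusted p = 0.07 with an estimated correlation) and early response genes (6.29e-06, 2 of 16, alone 6; adjusted p = 0.085 with an estimated correlation). Also higher were MHC class I (0.00909, alone 2; adjusted p = 0.0878 with an estimated correlation), MHC class II (0.00909, alone 3 higher and 1 lower; adjusted p = 0.352 with an estimated correlation) and thymocyte genes (0.0362; adjusted p = 0.352 with an estimated correlation). Lower were ciliated (0.00113, alone 2; adjusted p = 0.07 with an estimated correlation), tuft (0.00909; adjusted p = 0.07 with an estimated correlation) and endothelial genes (0.0218; adjusted p = 0.101 with an estimated correlation). The other 20 lists, PRC2 and HOX genes among them, had adjusted p values from 0.0819 to 0.997. In 9 of those, the B cell, CDK inhibitor, chemokine, fibroblast, mTEC maturation, muscle, p53 target, PRC2 and thymus organogenesis lists, the median, mean, camera and fry did not all have 1 sign.

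Bulk ZsGpos and ZsGneg cells, sorted from mutant mice of the same strain, were compared to ask what accompanied reporter activity within the mutant. H2-Aa was 2.46-fold lower in ZsGpos, at 3451 ± 124.3 against 8500 ± 1320 CPM (SD, n = 4 each; log2 -1.30, SE 0.121, adjusted p = 0.000185). Cd74, the invariant chain that guides MHC class II to its peptides, fell from 28760 ± 7760 to 10480 ± 761 CPM (log2 -1.46, SE 0.168, adjusted p = 0.000662), and Ctss, the protease that trims it, from 570.1 to 269.5 CPM (log2 -1.08, SE 0.197, adjusted p = 0.00941). Krt5 rose from 308.5 ± 94.8 to 787.6 ± 97.2 CPM (log2 1.35, SE 0.225, adjusted p = 0.00539) and Hes1 from 57.6 to 186.7 CPM (log2 1.70, SE 0.317, adjusted p = 0.011).

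In this comparison 2.66% of the 18931 genes passed, of which 23.4% were higher in ZsGpos. Lower genes held Ccl5, a chemokine for T cells (1392 to 318.1 CPM, log2 -2.13, adjusted p = 0.00341), Psme2, a proteasome activator (777.1 to 326.4 CPM, adjusted p = 0.00851), B2m, the light chain of MHC class I (17650 to 12870 CPM, log2 -0.46, adjusted p = 0.0196), and Cdx1 (228.04 to 59.4 CPM, adjusted p = 0.00306). Sprr4 (0 against 13.9 ± 6 CPM, adjusted p = 0.00996), Cst9 (0.0379 against 31.6 CPM) and M1ap, a protein of meiotic cells (log2 -8.03, adjusted p = 0.00243), were close to absent in ZsGpos. Higher were Wnt4, a ligand of thymic epithelial development (3.79 to 45.6 ± 19 CPM, log2 3.59, adjusted p = 0.0148), the p53 targets Cdkn1a (62.6 to 178.2 CPM, adjusted p = 0.0359) and Zmat3 (19.4 to 107.3 CPM, adjusted p = 0.0151), Dclk1, a kinase of tuft cells (45.4 to 133.1 CPM, adjusted p = 0.0377), and the heat shock genes Hspa1a and Hspa1b (log2 1.93 and 2.35). Aire (248.05 against 143.1 CPM, log2 0.79, SE 0.221, adjusted p = 0.08) and Cd80 (26.3 against 102.2 CPM, log2 -1.96, SE 0.529, adjusted p = 0.0709) had no call, nor did Cdkn2a (log2 2.64, adjusted p = 0.564), Suz12 (0.97, 0.277), Psmb11 (4.22, 0.265) or the remaining named genes. H2-Aa, Cd74, Ctss, Krt5, Hes1, Ccl5, Psme2, Cdx1, Sprr4, Cst9, M1ap, Hspa1a and Hspa1b stayed past the threshold whichever unit was left out. Wnt4 did not without ZsGpos 02 or 04 (0.0512 to 0.0609) or Zmat3 without ZsGpos 04 (0.0504). B2m lost its call without ZsGneg 03 or 04 or ZsGpos 01, 02 or 04 (0.0551 to 0.0827), Cdkn1a without any unit except ZsGneg 01 and ZsGpos 01 (0.0609 to 0.102), and Dclk1 without any except ZsGneg 03, ZsGpos 02 and WT 02 (0.0574 to 0.0994). The share past the threshold was 1.75 and 1.65% without ZsGpos 02 and 04, and 1.73, 1.71 and 1.75% without WT 01, 02 and 03. The share of reads outside genes was 33.9 ± 1.98% in ZsGpos and 22.2 ± 2.23% in ZsGneg, and with it as a covariate edgeR called 0 genes (826 at unadjusted p under 0.05); DESeq2 without the covariate called 10.5%, of which 49.8% were higher, so the excess of lower genes was lost.

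Camera called 9 lists between ZsGpos and ZsGneg. Wnt, Bmp and Notch signalling genes were higher (adjusted p = 1.55e-06, 2 of 33 members, Hes1 and Wnt4, alone 4 higher and 1 lower), the list that also passed with an estimated correlation (0.0418). MHC class II genes were lower (8.59e-05, 6 of 13 members, alone 8; adjusted p = 0.137 with an estimated correlation), and so were tissue-restricted antigens (0.00231, 4 of 37, alone 5; adjusted p = 0.137 with an estimated correlation) and cell cycle genes (0.00348, none of 34; adjusted p = 0.232 with an estimated correlation). Higher were early response genes (1.29e-05, 4 higher and 1 lower of 16, alone 12 and 1; adjusted p = 0.137 with an estimated correlation), developmental transcription factors (0.0129, 1 lower of 85, alone 3 higher and 1 lower; adjusted p = 0.137 with an estimated correlation), p53 targets (0.0188, 3 higher and 1 lower of 22, alone 7 and 1; adjusted p = 0.137 with an estimated correlation), HOX genes (0.0368, none of 21, alone 1; adjusted p = 0.137 with an estimated correlation) and PRC1 genes (0.0368, none of 20; adjusted p = 0.387 with an estimated correlation). The other 21 lists had adjusted p values from 0.118 to 0.924. In the ciliated, interferon, keratinised, neuroendocrine and PRC2 lists among them the median, mean, camera and fry did not all have 1 sign.

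Fos, Egr1 and Clu were called in both ZsGpos and ZsGneg cells against WT. In 20 simulations, unchanged groups against the same WT units gave 0 shared genes. Unchanged groups yield few calls, so this value was nearly fixed in advance. Independent lists of these sizes would share 0.0089 higher genes over 18931 genes. Across 12979 genes, which are not independent replicates, the log2 fold changes of the comparisons had a correlation of 0.162 and a covariance of 0.25. Unchanged groups gave a mean of 0.59 and 1.07 by the shared controls alone, above both observed values. Simulated values this far above the observed ones may overstate what the shared controls gave here. They can therefore not show whether the fold changes agreed beyond the shared controls. The 3 WT units cannot be halved and the simulations held no real changes, so whether shared WT values added to the shared calls was not settled.

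Small pools of 100 mTEChi cells from 1 plate were compared in the same 3 ways, as a second measure of the bulk differences. WT wells held 10332 to 50262 gene counts, ZsGneg wells 21550 to 71867 and ZsGpos wells 68939 to 180374. In the single cells of the same plate, WT had high Xist and both Eed groups high Y-linked genes. Sex-linked expression and genotype can therefore not be told apart on it. Ly6a, a surface antigen of progenitor and interferon-exposed cells, stood at 3481 CPM in ZsGpos and 451.98 CPM in WT wells (log2 3.06, SE 0.499, adjusted p = 0.00223, n = 3 wells each). Ccnd2, a cyclin of the G1 phase, fell from 1419 to 151.95 CPM (log2 -3.20, SE 0.515, adjusted p = 0.00223). Ccl25, the chemokine that draws T cell progenitors to the thymus, was higher in ZsGpos than in WT (log2 2.79, adjusted p = 0.00775) and in ZsGneg (log2 2.65, adjusted p = 0.00775), and Hspb1, a small heat shock protein, was higher in ZsGneg than in WT (3742 against 144.9 CPM, log2 5.21, adjusted p = 0.00231). These 4 genes were chosen after their values were seen. Tff3 had no count in ZsGpos against 199.3 CPM in WT wells (adjusted p = 0.0396), a call lost without any 1 well except ZsGneg 1 (0.0597 to 0.15). Fcer1g fell from 614.3 CPM in ZsGneg to 50.2 CPM in ZsGpos (log2 -3.66, adjusted p = 0.00581), but not without ZsGneg 2 (0.0928). Against bulk, Krt5 stood at log2 0.04 (bulk 2.66; adjusted p = 0.982) and Reg3g at 1.27 (bulk -2.01; 0.328) in ZsGpos against WT. Clu stood at -2.09 (bulk 1.10; 0.101) in ZsGneg against WT. Among other genes named in bulk, Fos had log2 fold changes of 4.22 in ZsGpos and 3.43 in ZsGneg against WT without passing the threshold (adjusted p = 0.0827 and 0.262). H2-Aa showed 0.25, 0.15 and 0.11 in the 3 comparisons, without a call and with no fall in ZsGpos (adjusted p = 0.806, 0.936 and 0.915), and Cd74 stood at log2 0.14 between ZsGpos and ZsGneg (adjusted p = 0.904). Of 731 genes tested, 20 passed in ZsGpos against WT (13 higher), 4 in ZsGneg against WT and 27 in ZsGpos against ZsGneg (16 higher). Xist was among the calls of both comparisons against WT. Of the bulk calls tested here, 62.8, 85.7 and 55.7% had the bulk direction in the 3 comparisons. The counts depended on single wells: ZsGpos against WT gave 32 and 11 genes without ZsGneg 1 and 3, and 10, 8 and 3 without WT 1, 2 and 3. ZsGneg against WT gave 9 and 1 without ZsGneg 1 and 2, 18 without ZsGpos 1, 1 without WT 2, and 0 without WT 1 or WT 3 (edgeR, 14.2 and 10.8% of the tested genes at unadjusted p under 0.05; DESeq2 with all wells gave 3). ZsGpos against ZsGneg gave 10 and 17 without ZsGneg 3 and ZsGpos 2, and 0 without ZsGneg 2 (edgeR, 12.2% of the tested genes at unadjusted p under 0.05; DESeq2 with all wells gave 32).

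Single ZsGpos and WT mTEChi cells were compared over 4 plates, each group being 1 sample. Stmn2 stood at 116.2 CPM in ZsGpos and 9.65 CPM in WT, and was detected in 42.9 and 14.7% of cells. Angpt2, a vascular growth factor, had 98.1 against 3.04 CPM, the myelin protein gene Pmp22 58.4 against 2.10 CPM and the matrix protein gene Thbs2 55.6 against 5.66 CPM. Among the lower genes were antigens of single tissues: Fabp2, a fatty acid carrier of the gut, had 0.0413 CPM in ZsGpos and 113.7 in WT, Anxa10, a gastric annexin, 2.46 against 100.7 CPM, and Cyp2a5, a liver cytochrome, 19 against 290.4 CPM. Of all genes, 10 stood at least 8-fold above the other 4 single-cell sets in ZsGpos, Umod of the kidney and Pth of the parathyroid among them (chosen after their values were seen). In WT mTEChi cells 8 genes stood as far above the other sets, Fabp2 and Cyp2a5 among them, and in ZsGneg cells 0. H2-Aa, at 11357 against 12447 CPM (log2 ratio -0.13), and Aire, at 876.0 against 954.0 CPM (-0.12), were close to WT, while Cd80 had 18.8 against 38.8 CPM. Ccl21a, the chemokine of immature mTECs, had 11.7 against 4.72 CPM and was detected in 48.4 against 21.3% of cells, with reads that cannot be told from those of its near-identical copies. Cdkn2a had 0.881 against 0.481 CPM, in 10.1 against 2.80% of cells (5.53 against 1.75% thinned).

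By list, mTEC-low genes had a median log2 ratio of 1.07 in ZsGpos against WT, with 12 of 14 members higher, above all random lists, for example Krt5 (996.2 against 481.4 CPM) and Krt14 (1158 against 458.4 CPM). Cells with at least 3 mTEC-low markers made up 74.7% of ZsGpos and 43% of WT cells thinned (88 and 58.7% unthinned), and those with at least 3 markers of the Aire stage 79.3 and 89.9% (86.6 and 94.8%). Whether the sort on MHC class II or the loss of wells changed these shares was not tested: 40.2% of ZsGpos and 57.7% of WT wells passed the filters, and 2 ZsGpos cells were left on plate D. Sex-linked genes differed as well, with the Xist pattern in WT and the Y-linked pattern in ZsGpos cells on plates A to C. HOX genes had a median of 0.94 (13 of 16 higher) and Wnt, Bmp and Notch genes 0.53 (25 of 33). Interferon response genes had 0.56 (23 of 26), developmental transcription factors 0.24 (44 of 79) and early response genes 0.43 (10 of 16). Each of these lists lay above 99% of random lists, as did fibroblast (0.94), B cell (0.84) and MHC class I genes (0.23). The 16 HOX members were low, with a summed level of 57.8 CPM in ZsGpos and 37.3 CPM in WT cells. Developmental transcription factors had a lower sum in ZsGpos despite the higher median, at 1029 against 1122 CPM. Tissue-restricted antigens had a median of -0.45 (13 of 38 higher), mTEC maturation -0.31 (3 of 21), cell cycle -0.31 (8 of 34), microfold -0.59 and myeloid genes -0.69, each below 99% of random lists. Muscle genes were at -0.51 with a mean of 0.21. MHC class II and tuft genes had medians of 0.00. The plates differed: tissue-restricted antigens had medians of 0.04, -0.47, 0.24 and -4.18 on plates A to D and microfold genes 0.06, -0.18, 0.34 and -6.29, the last from 2 ZsGpos cells. Maturation medians were 0.02, -0.24, -0.44 and -2.58, cell cycle -0.74, -0.05, -1.40 and -4.94 and myeloid 0.06, -0.48, -0.85 and -4.74. The mTEC-low medians were -0.26, 1.49, 1.08 and 2.15 and HOX medians 1.90, 1.32, 1.02 and -0.08 on plates A, B, C and D. Of the bulk calls, 84.7% (61 of 72) had the same direction in the single cells, against 56.9 and 72.2% on plates A and C alone.

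Single ZsGneg and WT mTEChi cells differed in early response genes, which were higher in ZsGneg. Dusp1 had 175.2 against 33 CPM (log2 ratio 2.37), Fos 479.8 against 93.3 CPM and Mdk 235.9 against 78 CPM. Cdkn1c, an imprinted inhibitor of the cell cycle, had 12.6 against 178.7 CPM (log2 ratio -3.72), and the olfactory cytochrome Cyp2g1 had a ratio of -4.10. Aire (0.29) and H2-Aa (0.02) were close to WT, and all 8 bulk calls had the bulk direction. The early response list had a median of 0.97 (15 of 16 higher; 0.99, 0.20, 0.15 and 2.22 on plates A to D), MHC class I 0.30 (15 of 15), MHC class II 0.21 (12 of 13), B cell 0.83 (6 of 7) and thymocyte genes 0.45 (13 of 18). Thymocyte medians were 2.76, -0.65, 0.59 and -0.05 on plates A to D, and -0.38 on the plates of 1 sex-linked pattern. Cells with at least 3 B cell markers made up 4.24% of ZsGneg and 0.699% of WT cells thinned (4.85 and 1.75% unthinned). Those with at least 3 thymocyte markers made up 8.18 and 2.45% (9.70 and 4.196% unthinned). Tuft genes had a median of -1.12 (2 of 16 higher), microfold -0.72, muscle -1.04 and cTEC genes -0.43, all below 99% of random lists. On plates A to D the tuft medians were 0.10, 0.38, -0.78 and -2.99. Microfold genes had 0.15, -0.35, 0.20 and -2.21, and muscle genes 1.13, -0.64, -2.06 and -0.73. The cTEC medians were -0.07, 0.27, -0.25 and -0.53.

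Between single ZsGpos and ZsGneg cells, Pmp22 (58.4 against 0.689 CPM), Cdkn1c (172.8 against 12.6 CPM) and the annexin Anxa8 (177.8 against 23.3 CPM) were among the genes higher in ZsGpos. Ccl2, a chemokine that draws monocytes, had 17.6 against 89.1 CPM. H2-Aa was close between the groups (log2 ratio -0.15), unlike in bulk, and the MHC class II list had a median of -0.07. Tuft genes had a median of 1.19 (16 of 17 higher), mTEC-low genes 0.72 (13 of 14), HOX genes 0.59 (12 of 17) and developmental transcription factors 0.42 (43 of 70). Early response genes had a median of -0.59 (3 of 16 higher), the opposite of bulk, but their medians on single plates spanned 2.65 and went both ways. Cell cycle genes had a median of -0.34 (7 of 34 higher). Of the bulk calls, 70.6% had the same direction.

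**Figure D2:**
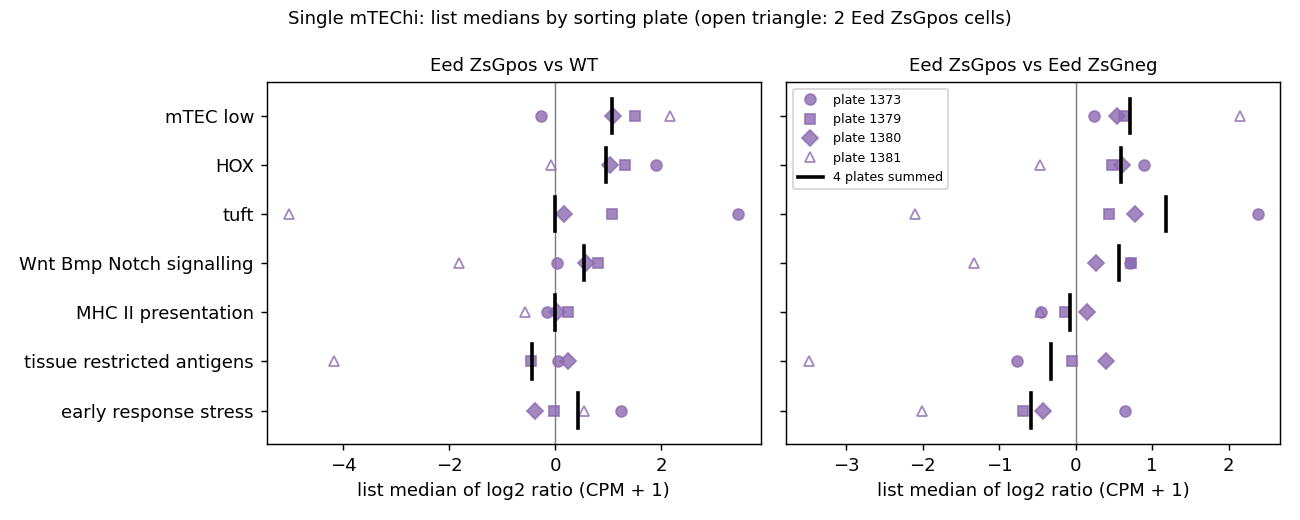
Median log2 ratio of 7 gene lists in single mTEChi cells on each plate (markers) and over the 4 plates summed (black bars), for ZsGpos against WT and against ZsGneg; the open triangle is the plate with 2 ZsGpos cells. Several lists changed sign between plates, early response genes among them.

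Single Eed and WT cTECs were compared to ask which genes depended on Eed in the cortex, with 1 set of wells per genotype. Psmb11, the thymus-specific proteasome subunit that shapes positive selection, had 34.3 CPM in Eed and 790.0 CPM in WT cells. It was detected in 9.31 and 63.2% of these cells. Psmb11 encodes beta5t, after which the Cre driver of the Eed strain is named. For this gene an effect of the driver can therefore not be told apart from one of Eed. Prss16, a serine protease of cTECs, had 218.8 CPM in Eed against 3443 CPM in WT cells. Foxn1, the factor that specifies thymic epithelium, had 75.5 against 260.7 CPM. Cdkn2b, an inhibitor of CDK4 and CDK6 and a known Polycomb target, had 42.7 against 3.23 CPM, in 45.6 and 3.31% of cells. Cdkn2a had 1.77 CPM (1.57 to 1.99) in Eed cells, in 12.6% of them (4.80% thinned), and no count in WT cells, which allows a share of up to 1.10% of cells with a count and sets no limit on cells that express the gene.

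High ratios were those of Cyp2f2, a cytochrome of airway cells (2171 against 2.61 CPM), Krt15, a keratin of basal progenitors (1137 against 1.25 CPM), and Prrx1, a homeobox factor of mesenchyme (190.01 against 0.0797 CPM). Igf2 had 96.3 against 0.0217 CPM and Osr2 108.1 against 0.261 CPM. Among the low ratios were those of Ccl22, a chemokine of mature mTECs and dendritic cells (0.528 against 238.2 CPM), and Acta2, smooth muscle actin (20.9 against 699.2 CPM). Rps16, a ribosomal protein gene with many processed copies, was at 10.3 against 482.4 CPM, and at 10.3 to 20.1 CPM over the other 4 single-cell sets, so the WT cTEC set stood apart in it.

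The cTEC list had a median log2 ratio of -2.18, with 15 of 18 members lower in Eed cells, below all random lists, and it included Ccl25 (71.2 against 1703 CPM) and the Notch ligand Dll4 (6.61 against 93.4 CPM). HOX genes had a median of 2.30 (19 of 23 higher), developmental transcription factors 2.20 (42 of 52) and CDK inhibitors 2.04 (5 of 6), all above 99% of random lists. Hoxa7 had 17.8 against 1.2 CPM, Gata3, a factor of early T cells and many epithelia, 59.1 against 3.14 CPM in 55.9 and 6.25% of cells, and Cdkn1a 229.04 against 27.1 CPM. Fibroblast genes had a median of 2.03 (11 of 11 higher), with Dcn at 4516 against 1492 CPM and Col3a1 at 456.1 against 18.4 CPM. The genes given as examples from lists here were chosen after their values were seen. Early response genes had a median of 1.37, B cell genes 1.21, mTEC-low genes 0.82, p53 targets 0.50 and Wnt, Bmp and Notch genes 0.41, each above 99% of random lists. Lower were interferon response (-0.88, 24 of 26 lower), MHC class II (-0.77, 12 of 13 lower, H2-Aa at 3053 against 4994 CPM), and mTEC maturation genes (-1.05). Neuroendocrine genes had a median of -1.63 and a mean of -0.48, from 5 expressed members (2 higher and 3 lower). Medians of -0.70 for tissue-restricted antigens, -0.96 for ciliated, -0.45 for chemokine, -0.21 for cell cycle and -0.29 for MHC class I genes went the same way. PRC2 (-0.10), PRC1 (0.10), keratinised (0.46), tuft (0.85), muscle (0.72), microfold (0.21), endothelial (0.09), thymocyte (0.33) and thymus organogenesis genes (-0.19) lay between. Myeloid genes had a median of -0.42 and a mean of 0.05, and the erythroid list held too few expressed members. Cells with at least 3 cTEC markers made up 81.4% of Eed and 97.8% of WT cells thinned (90.7 and 99.6% unthinned), and those with at least 3 fibroblast markers 33.3 and 1.84% (50.8 and 4.04%). The filters passed 86.7% of Eed and 70.8% of WT wells. No plate is known to hold both genotypes, so genotype and set of wells cannot be told apart.

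**Figure D3:**
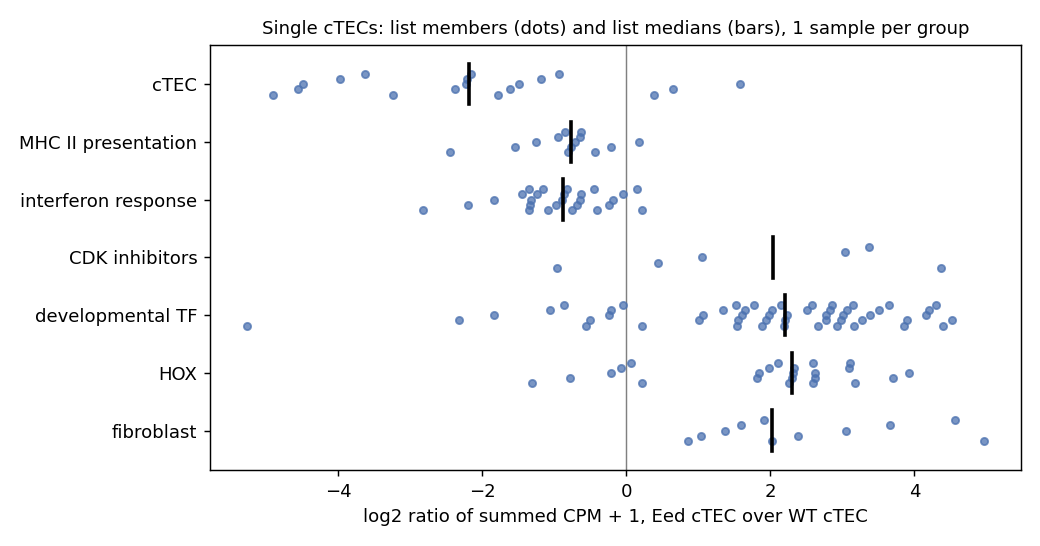
Log2 ratio of summed CPM, with 1 CPM added to both sides, between Eed and WT single cTECs for the members of 7 gene lists (dots) with list medians (bars). Members of the cTEC list lay mostly below 0, and those of the HOX, developmental transcription factor and fibroblast lists mostly above.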

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

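The covariate for reads outside genes, the tests of myeloid cells, of Aire-stage cells, of a fixed difference in early response genes and of a set difference in cTECs, and the splits of the units for counts of genes, were chosen after the results they concern were seen.

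For 7 measures of named genes in the bulk ZsGpos or ZsGneg group, 1 library lay far from the other 3 by Dixon's criterion. Chance would give about 6 among the measures tested, since the criterion picks 1 in 20 groups, so the number of such libraries is no pattern by itself. Ezh2, the methyltransferase of PRC2, was lowest in ZsGneg 01, at 33.39 CPM against 75.67 to 83.49 in the others. Cd80 was highest in ZsGneg 04 (157.1 CPM against 79.92 to 86.3), and Dclk1 in ZsGneg 03 (74.06 CPM against 33.1 to 37.93). Egr1 was highest in ZsGneg 01 (266.4 CPM against 186.7 to 197.3) and lowest in ZsGpos 01 (225.6 CPM against 454.5 to 494.7). ZsGpos 01 was also highest for Pter, a phosphotriesterase-related enzyme (120.7 CPM against 0.474 to 13.94), and for Laptm5, a lysosomal protein of blood cells (202.01 CPM against 133.4 to 142.3). ZsGpos 01 thus accounts for 3 of the 7 and ZsGneg 01 for 2.

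Opposite directions between cTECs and every plate of mTEChi cells appeared for a pair of named genes in single cells. Ezh2 had a log2 ratio of 0.66 in Eed cTECs against WT, and of -0.32 in ZsGpos mTEChi cells against WT, from -0.81 to -0.36 on plates A to C and -5.42 on plate D with its 2 ZsGpos cells. Fezf2, a regulator of self-antigens in mTECs, had 0.12 in cTECs and -0.31 in mTEChi cells, from -0.50 to -0.29 on plates A to C and -2.58 on plate D. Cdkn2b had 3.37 in cTECs and -0.31 over all mTEChi plates, but 1.03 on plate A. Each group was 1 sample, so these differences were not tested.

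Of 14 wells labelled as having no template, 3 on plate C held 51838, 67466 and 73567 gene counts and between 1783 and 3497 genes, above the filter for cells. The others held a median of 87 counts. Carry-over and a wrong assignment of well or index were not tested, and these wells entered no comparison.

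MHC class II genes were lower in bulk ZsGpos than in ZsGneg libraries, by -1.30 on the log2 scale for H2-Aa. Fewer Aire-stage cells in ZsGpos would lower maturation genes about as far, and this stays open: the median of the 21 tested members was -0.051, a distance from H2-Aa hardly above the interquartile range of 1.24, and in single cells it was -0.35, with Aire-stage cells at 79.3% of ZsGpos and 90.3% of ZsGneg, while Aire itself went against it in bulk (248.05 against 143.1 CPM, log2 0.79, SE 0.221). A difference in read quality stays open as well: the share of reads outside genes was 31.2 to 35.9% in ZsGpos and 18.9 to 24.04% in ZsGneg, and with it as a covariate H2-Aa stood at -1.27 (adjusted p = 1, SE 0.311 in place of 0.121). More myeloid or dendritic cells in ZsGneg also stay possible, although TECs were sorted: 72.7% of the 11 tested members were lower in ZsGpos (Lyz2 346.6 against 571.5 CPM, Laptm5 153.98 against 343.6 CPM, Fcer1g 8.03 against 51.7 CPM), but Csf1r had 11 against 0.157 CPM, and of the 13 list genes 9 reached 5 CPM in WT mTEChi and none is in another list. The deletion of Eed is an untested biological explanation that may act beside these, and the single cells and small pools did not show a fall of that size in H2-Aa.

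Early response genes were higher in bulk ZsGpos than in ZsGneg libraries, with Fos at 676.2 against 258.6 CPM. A fixed difference between these cells stays open: in single cells the median of the list was -0.59, below all random lists, but 0.05 on the plates of 1 sex-linked pattern, and in the small pools Fos, Egr1 (284.6 against 88.9 CPM) and Hspa1b (74.8 against 6.42 CPM) went the bulk way. Handling that differed between sorts, for example the time from digestion to lysis, could give such differences: the list medians on single plates spanned 2.65 and went both ways, also without the plate with 2 ZsGpos cells (0.64 to -0.69). Whether this holds for the bulk sorts was not measured.

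HOX genes and developmental factors were higher and cTEC genes lower in the Eed set of single cTECs. Fibroblasts among the Eed cells were tested by leaving out cells that showed at least 3 fibroblast markers after thinning. This left 66.7% of Eed and 98.2% of WT cells. The median over 75 members was then 2.20 against 2.24 with all cells, and the cTEC list stood at -1.92, so the cells left out did not carry the pattern. Unthinned, 50.8% of Eed cells showed as many markers, so some of these cells remained and the explanation stays open in part. Dcn was detected in most WT cells as well, and of the 11 fibroblast genes 6 reached 5 CPM in WT cTECs and 1 is in another list. A difference between the sets in sequencing or counting cannot be told apart from genotype, since no plate is known to hold both: the log2 ratio of the summed pseudogene levels was 0.93, and in WT cTECs Rps23 stood at 505.7 CPM and mt-Co3 at 4.16 CPM against at most 34.4 and at least 288.2 CPM in the other sets. The loss of PRC2, which silences HOX genes in many tissues, may be a further cause and was not tested apart from the set.

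The bulk units were also split into groups of the same sizes. For the counts of genes, 1 of 35 splits, the real one, gave as many in each comparison (72 genes against at most 1 in another split, 8 against at most 1, and 2.66% of tested genes against at most 3 genes). This is a share under 0.05, but the smallest these splits can give, and it was not corrected for the number of comparisons. For the lists, chance was not excluded in ZsGpos against WT (13 lists, 2 of 35 splits as large, highest other 16) or in ZsGneg against WT (10 lists, 2 of 35, highest other 11). In ZsGpos against ZsGneg the real split alone gave as many (9 lists, 1 of 35), but another split came close with 8. In the small pools the 10 splits are too few for a share under 0.05; the real counts of 20, 4 and 27 stood against at most 1 in any other split.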

How the results depend on the processing

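The factor for sex-linked expression, the covariate for reads outside genes, the use of 1 WT library per number, the small pools of at least 10000 counts and the plates of 1 sex-linked pattern were chosen after the data were seen. The share of tested genes past the threshold in bulk ZsGpos against WT (0.38%) became 2.86% with DESeq2, 0.831% without the filter on low counts, 1.67% with 9 WT libraries as separate samples, 0.678% with only the compared groups and 0.037% with the covariate. In ZsGneg against WT (0.042%) these gave 2.73, 0.368, 0.768, 0.006 and 0%, the sex-linked factor 0.005% and 1 WT library per number 0% (edgeR, 925 genes with the covariate and 1674 with 1 library at unadjusted p under 0.05). In ZsGpos against ZsGneg (2.66%) DESeq2 gave 10.47%, no filter 2.42% and the covariate 0% (edgeR, 826 genes at unadjusted p under 0.05). The 9 libraries raise the number of WT samples by construction, and for the other settings the cause was not tested.

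Whether the replicate number pairs the samples could not be told. With it as a replicate block 0.301, 0.005 and 1.81% of genes passed, and 13, 10 and 10 lists.

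An estimated correlation left 5, 0 and 1 of the 13, 10 and 9 camera lists. In ZsGneg against WT, fry called 16 lists moving 1 way (3 higher and 13 lower, against 7 and 3 by camera) and 18 in either direction (6 and 12), and 20 in either direction in ZsGpos against ZsGneg, because it does not compare a list with other genes. In ZsGpos against WT fry gave 6 lists higher and 9 lower, against 9 and 4 by camera.

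Small pools without the filter gave 53, 18 and 50 genes in place of 20, 4 and 27. With all 15 wells and no plate term ZsGpos against WT gave 50 and ZsGneg against WT 12, and wells of at least 10000 counts with a plate factor gave 13 in ZsGpos against WT.

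The share of bulk calls with the same sign in single cells was 56.9% on plate A and 72.2% on plate C for ZsGpos against WT (84.7% over all plates). For ZsGpos against ZsGneg (70.6%) it was 63.7, 50.4 and 53.2% on plates A, C and D, 61.3% with equal plate weights and 55.4% on plates of 1 sex-linked pattern. The log2 ratio of Eed in cTECs (-0.68) was -0.55 as a mean over cells and -0.53 thinned.

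Leaving out 1 unit gave 0.044% (without WT 02) to 0.5% (without ZsGneg 04) in bulk ZsGpos against WT, 0% (without ZsGneg 01; 1944 genes at unadjusted p under 0.05) to 0.027% in ZsGneg against WT and 1.65% (without ZsGpos 04) to 2.73% in ZsGpos against ZsGneg, with 10 to 16, 7 to 11 and 6 to 10 lists. Small pools gave 3 (without WT 3) to 32 (without ZsGneg 1), 0 (without WT 1) to 18 (without ZsGpos 1) and 0 (without ZsGneg 2) to 38 genes.

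Of 2237 values of named bulk genes under the other settings, 1799 kept their side of the threshold, 10 gained a call and the rest lost one. Those that kept their side include genes without a call in the main fit, so this share does not measure how stable the bulk calls were. Most of the lost calls came from leaving out 1 unit, where more values of called genes kept the call than lost it. With the covariate for reads outside genes all but 3 values of called genes lost it, and with DESeq2 none did. In the small pools 19 of 550 lost a call and 6 gained one, and for the called genes 17 of 27 values lost it when 1 well was left out. Of 1269 values in single cells, 800 moved beyond counting error. No called value changed sign. A fit on the first or second sequencing run alone was not run, since the repeat runs have no column. Depth limited the small pools, with 731 genes tested.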

Other observations

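Values in this part were taken from sets fixed in advance, and the test of plates of 1 sex-linked pattern was chosen after the data were seen.

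Mimetic cells of the medulla, which copy the programmes of tissues outside the thymus, were compared between the single ZsGpos and ZsGneg cells, each group being 1 sample, and no difference was tested. Dclk1, the tuft cell kinase, had 120.6 against 52.4 CPM, and the tuft list a median log2 ratio of 1.19, with 2.39, 0.43, 0.77 and -2.10 on plates A to D. Cells with at least 3 tuft markers made up 2.77% of ZsGpos, 0.606% of ZsGneg and 3.15% of WT cells thinned (4.15, 1.21 and 4.55% unthinned), with overlapping intervals of 1.02 to 5.92% in ZsGpos and 0.073 to 2.17% in ZsGneg. Endothelial genes had a median of 1.61 between ZsGpos and ZsGneg, with Plvap, a protein of fenestrated vessels, at 78.4 against 12.1 CPM, but one of -0.12 on the plates of 1 sex-linked pattern. Muscle genes had a median of 0.95, with -0.08, 0.00, 0.53 and -2.63 on plates A to D. The summed median thus lay above that of each plate, and the plates held unequal numbers of cells per group. Ciliated and neuroendocrine genes had medians of -0.78 and -0.40, but 0.77 and 0.69 on plate C, and neuroendocrine genes 0.55 on the plates of 1 sex-linked pattern. Myeloid genes had a median of -1.06 (2 of 12 higher), and cells with at least 3 myeloid markers made up 17.1% of ZsGpos, 27.9% of ZsGneg and 25.9% of WT cells thinned (24.4, 36.1 and 38.5% unthinned).

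Cells with at least 3 proliferation markers made up 17.1% of ZsGpos, 23.6% of ZsGneg and 24.1% of WT mTEChi cells thinned (22.6, 28.5 and 28.3% unthinned). Cells with at least 3 fibroblast markers made up 5.53% of ZsGpos, 0.303% of ZsGneg and 0.699% of WT cells thinned (7.83, 1.21 and 0.699% unthinned). Among cTECs, cells with at least 3 mTEC-low markers made up 89.5% of Eed and 68.8% of WT cells thinned (97.3 and 79% unthinned). The sort for mTEChi and the loss of wells, with 40.2% of ZsGpos, 70.4% of ZsGneg and 57.7% of WT wells passing, were not tested as causes of these shares.

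Sex-linked expression did not balance the groups. Of the bulk units, 2 of 3 WT units had high Xist and 1 high Y-linked genes, against 1 and 3 in each Eed group. In single mTEChi cells WT had the Xist pattern on all 4 plates, while ZsGpos had the Y-linked pattern on plates A, B and C, so no plate allowed a comparison of ZsGpos with WT within 1 pattern. Both cTEC sets had the Xist pattern. In the small pools Xist was called in both comparisons against WT. On plates A and C, where ZsGpos and ZsGneg shared a pattern, the tuft list had a median of 1.66 and the early response list 0.05, and 55.4% of the bulk calls had the bulk direction.

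Bulk libraries also differed in composition. Mitochondrial genes took 12.2 ± 2.51% of gene counts in ZsGpos, 6.70 ± 0.947% in ZsGneg and 7.41 ± 0.296% in WT units (SD, n = 4, 4 and 3). Spike-in RNA took a median of 0.899% of counts in Eed and 0.108% in WT cTEC wells, and from 37.2 to 39.8% in mTEChi wells. One small pool of ZsGpos cells on plate D held 68 gene counts.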
